A study of Mus musculus with 12 samples.

How the data were processed

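The series holds 12 Affymetrix mouse arrays of MMTV-c-Myc mammary tumours from female FVB mice, 6 with the Hunk knockout genotype and 6 with the wild-type genotype. Total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, per the labels. GCRMA is the only tool the submitters' processing notes name, with no version. The deposited values are log2 signals, 1 table of 22690 probe sets by 12 arrays without missing values, ranging from -0.07 to 14.72. The values were used as deposited, with no further background correction, normalization or pseudocount. Columns were matched to arrays through their sample labels, and 0 columns of the table were left unused. No scan date or other batch is given in the sources used here, so none could be tested. GCRMA pulls low signals toward a common floor, and so fold changes of transcripts near background are compressed or set by the floor.

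The highest of the Bacillus control probe sets on each array, which no mouse transcript matches, served as that array's background. A gene at or below it on every array of a group is given only a bound, the bright group's mean over the dim group's mean with each dim value raised to its array's background. No detection calls were used here. The background was 3.71 ± 0.15 (SD, n = 6) in the knockout and 3.60 ± 0.10 (SD, n = 6) in the wild type.

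Gene names came from the array platform's annotation, updated through gene identifiers in a RefSeq gene table of the GRCm38.p6 assembly, which served only for names and neighbours. Of the 22690 probe sets, 20393 had 1 symbol, 691 several and 1606 were not listed, 51 of the latter being among the 64 control probe sets. Of those with 1 symbol, 20364 were found in the table, and they named 12394 genes. Probe sets with several symbols are counted but not named. A gene is its probe set of highest mean over the 12 arrays. Of the genes past the threshold, 88 had more than 1 tested probe set and 1 of these had a probe set of opposite sign. 30 of them rest on a probe set ending in _x_at or _s_at, which can match related transcripts.

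Probe sets whose mean over all 12 arrays exceeded the median probe-set mean (3.98) were tested, with control probe sets left out. Hunk, with a mean of 3.58, lay below this filter and was tested in the fit over all probe sets. The test was limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, with group as the only term, and Benjamini-Hochberg adjustment over the probe sets or genes tested at a threshold of 0.05. 32 gene lists (986 members), fixed before the data were examined, were tested with camera at the preset correlation of 0.01 where at least 4 members passed the filter, with camera at an estimated correlation and fry beside it. List members were also adjusted over the list alone. Of the lists tested, 1 is not reported here. Named genes followed a rule fixed before the data were examined: Hunk, the 12 largest changes in each direction among genes past the threshold, up to 4 members of each list, and the most abundant member of each cell type list. Genes within 10 Mb of Hunk were compared with the others by Fisher's exact test. Permutation tests of single values were exact over all splits of 6 against 6, two-sided, with a smallest p of 0.00216.

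Whether the replicate numbers of the titles pair the arrays was looked at through the correlation of deviations from the group means. No clear pairing was seen, though no test was made and pairing is not excluded. The alternatives tried were other expression filters, eBayes without trend or robust, quantile normalization, median centring, array weights, the replicate number as a block, marker means and the first residual principal component as covariates, other gene summaries, other thresholds, an added offset, a test of each probe set on its own variance, 2 other windows around Hunk and leaving out each array. Averaging knockout arrays 4 and 5, a floor at array background, and beta-actin and adipocyte covariates were added after seeing the data.

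The steps were tested on simulated data for the comparison of knockout with wild type, drawn from the real probe sets' means and SDs, with 6824 genes passing the filter. Of 200 changed genes, those changed by 1 on the log2 scale and tested were recovered in 63.3% and those changed by 2 in 93.4%, with 3 false calls among 150. With no gene changed, 0 genes and 0 lists passed. The simulation drew probe sets independently and so leaves out correlation between genes. Figures were drawn with matplotlib 3.10.9.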

Results

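Gene expression was measured in mammary tumours of female FVB mice that carried a c-Myc transgene driven by the mouse mammary tumour virus promoter. 6 arrays held RNA of tumours lacking Hunk, a protein kinase of the Snf1 and AMPK family, and 6 that of tumours with intact Hunk. Each was an Affymetrix array of 22690 probe sets, and the deposited values were log2 GCRMA signals. The array medians over all probe sets lay between 3.87 and 4.10, and the number of arrays limits the precision. The labels number the arrays within each group but do not say that each came from a separate tumour or mouse. A numbered tumour below therefore means the sample on 1 array. The p-values of limma and of the permutation tests set differences against the spread between these samples, part of which may be technical. Camera sets a list against the other genes, and Fisher's test counts genes. Their p-values therefore do not measure how a list or a count varies between samples. A positive log2 change means a higher level in the knockout throughout.

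The first comparison concerned Hunk itself, since the targeted gene checks the labels. Its only probe set averaged 2.95 ± 0.17 (SD, n = 6) in the knockout and 4.21 ± 1.05 (SD, n = 6) in the wild type on the log2 scale. The signal was above array background in 4 of 6 wild-type tumours and in 0 of 6 knockout tumours, so the level was at least 1.41-fold lower in the knockout. The log2 difference of -1.26 (SE 0.39) had an exact two-sided permutation p of 0.0108, but the limma test adjusted over all 22626 probe sets gave p = 0.209. Wild-type tumour 6, at 2.99, lay within the knockout range. The targeted allele replaced the putative promoter and exon 1, on chromosome 16, and probe sets of this array type sit toward the 3' end of transcripts. The position of the Hunk probes against the deleted part was not checked here. Probes outside it would not read the deletion itself and may still read transcript.

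The main comparison asked which transcripts differed between Myc tumours with and without Hunk. The largest rises among genes past the threshold were of Cbr2 and Hp, and the largest falls of Dusp6 and Socs2. Cbr2, a carbonyl reductase, averaged 8.77 ± 0.75 (SD, n = 6) in the knockout and was at background in all 6 wild-type tumours, at least 35.8-fold higher (adjusted p = 1.47e-07). Hp, which encodes the haemoglobin-binding protein haptoglobin, was 80.1-fold higher (adjusted p = 8.3e-05). Dusp6, a phosphatase that switches off ERK, was 30.2-fold lower, and Socs2, a suppressor of cytokine receptor signalling, was 25.3-fold lower, each in 6 of 6 knockout tumours against every wild-type tumour.

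**Figure D1:**
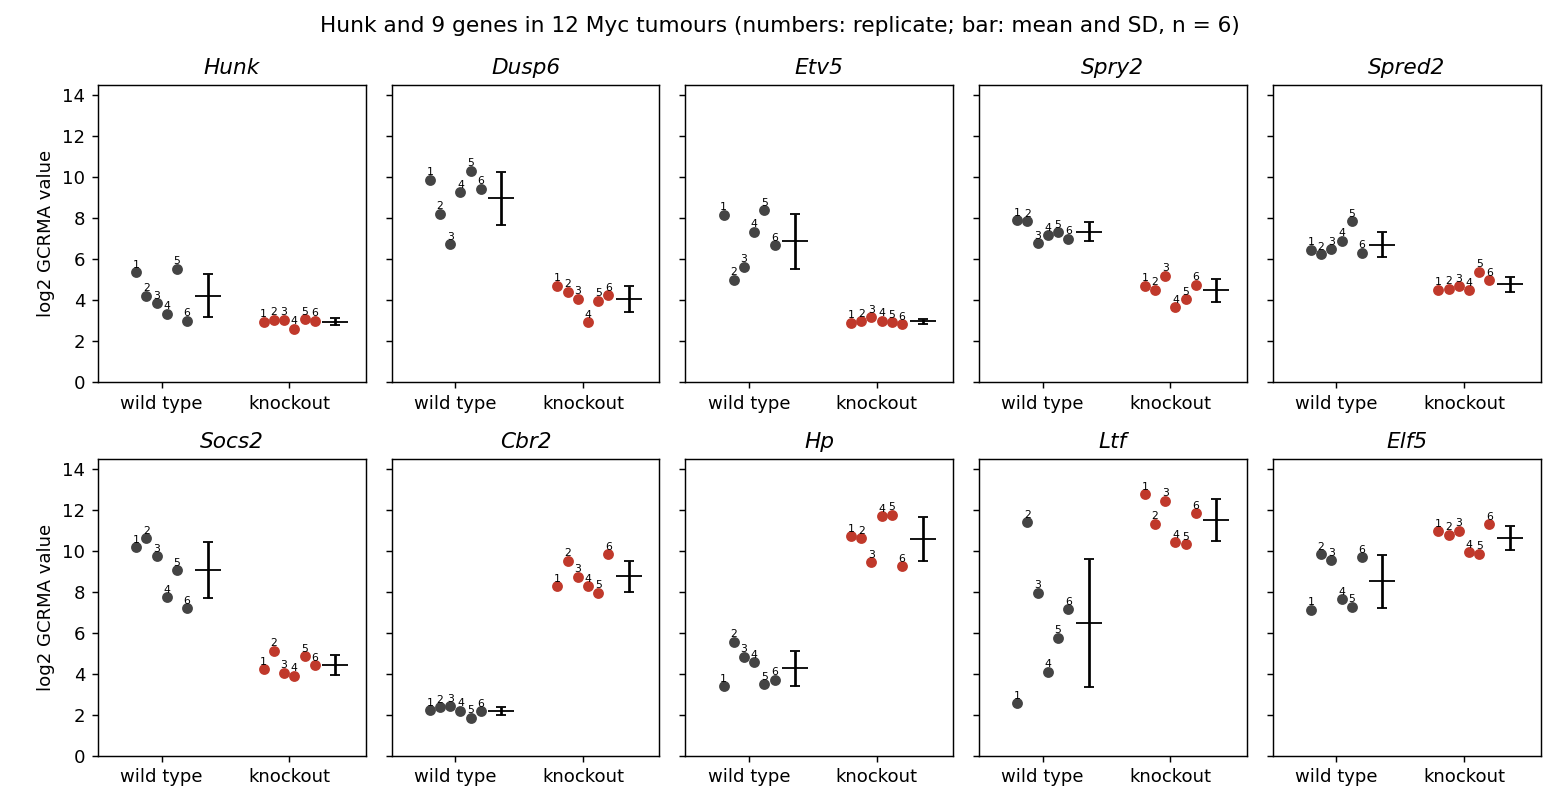
Log2 GCRMA value (vertical axis) of Hunk and 9 further genes in each of 6 wild-type (grey) and 6 knockout (red) tumours; the number beside each point is the replicate and the bar gives the mean and SD. Cbr2 and Hp were higher, and Dusp6, Etv5, Spry2, Spred2 and Socs2 lower, in every knockout tumour than in every wild-type tumour, while the groups overlapped for Hunk and Ltf.

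Of 6825 genes tested, 113 were higher and 115 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). At the level of probe sets, 133 were higher and 145 lower of 11313 tested. The changes were large, since 143 of the 228 genes moved at least 2-fold. Over all 6825 genes tested the groups did not overlap in 215, where chance gives 14.8 (a share of 0.00216), and 148 of the 215 were among the genes past the threshold. Besides Cbr2 and Hp, the 12 largest rises included the milk iron-binding protein lactoferrin, Ltf (log2 change 5.04, SE 1.20), the simple-epithelial keratin Krt19 (4.08, SE 0.97), the cytochrome P450 Cyp2f2 (3.96, SE 0.97) and the secreted Wnt modulator Sfrp2 (3.74, SE 0.89). Sfrp2 and Grb10 were at background in 5 of 6 wild-type tumours, and Cyp2f2 and Bdh1 in 3 of 6, so that the sizes of these changes rest in part on the background, and for Sfrp2 on wild-type tumour 3, at 7.06. Bdh1, Grb10, Chpt1, Chdh, Dcxr and Cryab rose by 2.43 to 2.95 on the log2 scale. Among the largest falls, Fam174b and Emid1 were at background in all 6 knockout tumours, at least 8.27-fold and 9.73-fold lower. Bex1, the collagen chain Col9a1, the integrin ligand Npnt, the kinase Stk26 and the mTOR inhibitor Deptor had log2 changes between -3.88 and -3.52. Bex1 was at background in 3 of 6 knockout tumours, so the size of its change rests in part on the background. Chn2, a Rac-inactivating protein, and Duoxa1 had changes of -3.13 and -3.05.

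The first principal component, 28.0% of the variance over tested probe sets, separated all knockout from all wild-type arrays (exact permutation p = 0.0022, the smallest 6 against 6 can give). A sign of RNA quality also differed between the groups. The 3' minus 5' difference of the beta-actin control probe sets was 1.51 ± 0.15 (SD, n = 6) in the knockout and 1.29 ± 0.05 (SD, n = 6) in the wild type (exact permutation p = 0.0108), and that of Gapdh was 0.20 ± 0.08 (SD, n = 6) against 0.09 ± 0.08 (SD, n = 6) (exact permutation p = 0.0455). Knockout tumours 4 and 5 were closer to each other than any other pair. The SD of their difference over probe sets was 0.338, against 0.531 for the next closest pair and a median of 0.783 for pairs of knockout arrays. With those tumours averaged as 1 sample, a choice made after seeing the data, 124 genes passed. The count fell to 94 without wild-type tumour 4, to between 131 and 149 without knockout tumours 4, 5 or 6 or wild-type tumour 5, to 72 with the beta-actin difference as a covariate (also chosen after seeing the data; the 228 genes kept a median of 104% of their log2 change and their sign, with standard errors 1.51 times larger) and to 4 with the mean of the luminal epithelial markers as a covariate, and of 50 named genes past the threshold 25 kept their call in every fit with 1 array left out. Those that did include Cbr2, Hp, Dusp6, Socs2, Etv5, Spry2 and Spred2, whereas Ltf kept its call in 1, Krt19 in 3 and Elf5 in 2 of 12 such fits. Centring the arrays on their medians changed the split from 113 higher and 115 lower to 157 higher and 100 lower. With the beta-actin covariate the split was 47 higher and 25 lower. Of those 72 genes only 46 were among the 228, so the split does not show how the calls were lost. The cell division list, described below, kept 30.9% of its mean change in that fit.

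Dusp6, Spry2, Spred1, Spred2 and Etv5 fell in the knockout. Of 23 measured members of the list of ERK feedback and immediate early genes, 5 fell, 0 rose and 18 did not pass, and adjusted over the list alone 10 fell and 2 rose. Spry2, an inhibitor of receptor tyrosine kinase signalling, was 7.27-fold lower (adjusted p = 0.000284), Spred2 was 3.85-fold lower (adjusted p = 0.00293) and Spred1 fell by 1.34 on the log2 scale (adjusted p = 0.0107). Etv5, an ETS transcription factor induced by ERK, averaged 6.86 ± 1.36 (SD, n = 6) in the wild type and was at background in all 6 knockout tumours, at least 8.84-fold lower (adjusted p = 0.00191). These 4 genes and Dusp6 were the 5 that fell. The other members were mixed, and those named here, like Spred1, fall outside the rule for named genes and were chosen after their values were seen. Adjusted over the list alone, Phlda1, Hbegf, Epha2, Ier3 and Ier2 were lower, and the growth-arrest gene Btg2 (log2 change 1.17) and the phosphatase Dusp1 (0.79) were higher, while Fos (0.40), Egr1 (-0.58), Jun (0.17) and Junb (0.06) did not pass. The list as a whole fell with a mean log2 change of -0.78 (camera, adjusted p = 0.00206), and 10 of its 23 members had a positive change. With an estimated correlation between genes the adjusted p was 0.0936. The change was not past the threshold among probe sets above the 75th percentile of the mean, where 11 members were tested (mean -0.16, adjusted p = 0.678). Dusp6, Etv5, Spry2 and Spred2 lay below that cut and were not among the 11. That fit therefore could not show their fall and covers only members of higher mean level.

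Markers of luminal and milk-producing epithelium changed unevenly. Elf5, a transcription factor of the alveolar lineage, was 4.34-fold higher (adjusted p = 0.049), and with Ltf it was among 2 of 15 milk and alveolar markers that rose, while Aldoc fell by 1.84 on the log2 scale and 12 did not pass. The list as a whole did not pass (mean log2 change 1.04, adjusted p = 0.135), but passed without knockout tumour 4 (adjusted p = 0.0263), knockout tumour 5 (adjusted p = 0.0249) or wild-type tumour 2 (adjusted p = 0.0405). It also passed with knockout tumours 4 and 5 averaged (adjusted p = 0.0262), with the first residual principal component (adjusted p = 0.03) or the luminal markers (mean 2.46, adjusted p = 0.000214) as a covariate, and its mean was negative with the beta-actin (-0.61, adjusted p = 0.455) or adipocyte covariate (-0.94, adjusted p = 0.227). Csn3, the kappa-casein gene and the marker with the highest mean, was 10.15 ± 3.95 (SD, n = 6) in the knockout and 12.40 ± 1.20 (SD, n = 6) in the wild type (adjusted p = 0.419). Of 10 luminal markers, Krt19 and the surface glycoprotein Cd24a (log2 change 0.87, SE 0.18) rose and 8 did not pass, and adjusted over the list alone 3 rose and 1 fell, with Muc1 at 2.35 and Kit at -2.95. The luminal list did not pass (mean 0.53, adjusted p = 0.206), and Krt18, the marker with the highest mean, had a change of -0.17 (adjusted p = 0.802). The epithelial junction list rose (28 measured members, mean 0.26, adjusted p = 0.0167, and adjusted p = 0.386 with an estimated correlation). Of these, 3 rose, 0 fell and 25 did not pass, and 6 rose adjusted over the list alone. Its adjusted p was 0.114 with no expression filter, 0.258 with the luminal markers as a covariate and 0.0723 without knockout tumour 1. The 3 were the desmosomal protein Pkp2 (2.57-fold), the tight-junction protein Tjp3 (2.94-fold) and the epithelial splicing factor Esrp2 (1.68-fold).

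The cell division list fell and the hypoxia and glycolysis list rose by camera with the preset correlation. Of 39 cell division genes, 38 had a negative change, 5 fell and 34 did not pass, and 11 fell adjusted over the list alone (mean log2 change -0.54, adjusted p = 1.05e-09, and adjusted p = 0.386 with an estimated correlation). Cenpf, a kinetochore protein, fell by 1.16 on the log2 scale (SE 0.23), the spindle motor Kif11 by 0.71 (SE 0.14), the checkpoint protein Mad2l1 by 0.89 (SE 0.20) and Cdc20, an activator of the anaphase-promoting complex, by 0.82 (SE 0.15). With the beta-actin difference as a covariate the mean change of the list was -0.17 (adjusted p = 0.156). Of 30 hypoxia and glycolysis genes, 7 rose, 1 fell and 22 did not pass, and adjusted over the list alone 16 rose and 3 fell (mean 0.42, adjusted p = 0.000173, and adjusted p = 0.386 with an estimated correlation). Ddit4, a stress-induced inhibitor of mTORC1, was 3.47-fold higher, the endoplasmic reticulum oxidase Ero1a 1.92-fold, and the glycolytic enzymes Ldha 1.53-fold and Pgam1 1.49-fold. Aldoc, the aldolase isoform that also stands in the milk list, was the member that fell. The MYC target list fell by the same test (37 measured members, mean -0.23, adjusted p = 0.0018, and adjusted p = 0.716 with an estimated correlation). Of these, Fkbp4 fell by 0.60, Ldha rose and 35 did not pass, and adjusted over the list alone 4 fell and 1 rose, among them the nucleolar genes Npm1 (-0.43) and Nop58 (-0.59). Myc, looked at after the values were seen because it is the transgene's gene, had a log2 change of -0.25 (SE 0.20, adjusted p = 0.490).

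**Figure D2:**
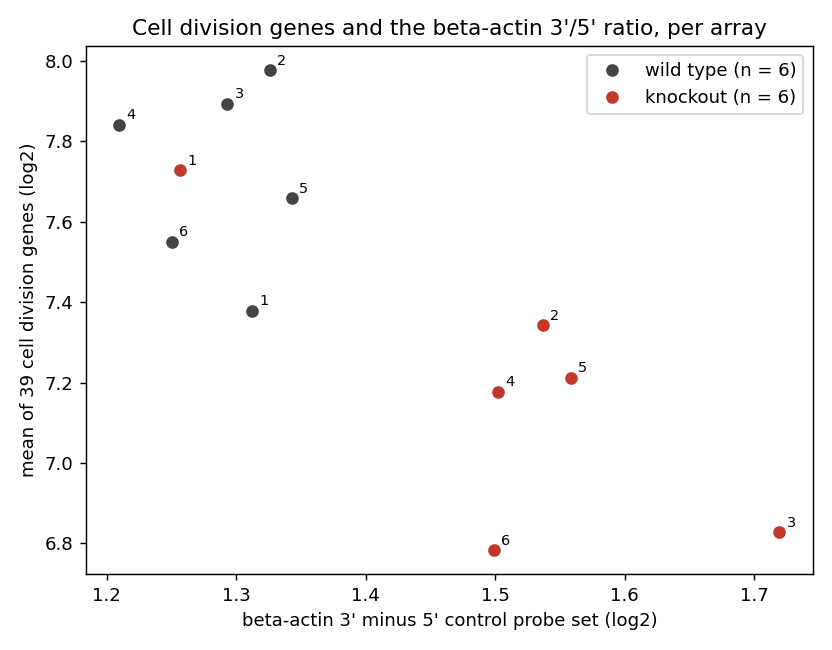
Mean log2 value of 39 cell division genes (vertical axis) against the 3' minus 5' difference of the beta-actin control probe sets (horizontal axis, log2) in 6 wild-type (grey) and 6 knockout (red) tumours, numbered by replicate. Knockout tumours 2 to 6 had both a larger beta-actin difference and a lower mean than all wild-type tumours, and knockout tumour 1 lay among the wild type.

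Lipid and tissue-composition lists moved as follows. The lipid and sterol synthesis list rose (29 members, mean log2 change 0.39, adjusted p = 0.0015, and adjusted p = 0.386 with an estimated correlation). None of its members passed over all genes, and 2 rose adjusted over the list alone, the fatty acid desaturase Scd2 (0.80) and the sterol enzyme Msmo1 (0.85). It did not pass with array weights (adjusted p = 0.0971). The adipocyte list rose (9 members, all positive, mean 0.99, adjusted p = 0.0018, and adjusted p = 0.386 with an estimated correlation). Of these, the triglyceride lipase Pnpla2 rose by 0.67 on the log2 scale and 8 did not pass, and 2 rose adjusted over the list alone, Pnpla2 and Thrsp (2.27), a gene that also stands in the lipid list. Fabp4 (1.51) and Car3 (2.36) did not pass. The fibroblast and matrix list rose (17 members, mean 0.41, adjusted p = 0.0018, and adjusted p = 0.687 with an estimated correlation) with 0 members past the threshold either way, such as Col3a1 (0.94, adjusted p = 0.0691) and Fbln2 (-1.79, adjusted p = 0.172). The macrophage list fell (21 members, mean -0.28, adjusted p = 0.0125, and adjusted p = 0.579 with an estimated correlation), again with 0 members past the threshold, such as C1qa (-0.52) and C1qb (-0.66), and the list did not pass without knockout tumour 2 (adjusted p = 0.0904) or knockout tumour 5 (adjusted p = 0.0538), with the fibroblast markers as a covariate (mean -0.11, adjusted p = 0.201), with the adipocyte markers as a covariate (adjusted p = 0.107) or among probe sets above the 75th percentile (adjusted p = 0.142). With the beta-actin difference as a covariate the adipocyte list had an adjusted p of 0.451, the macrophage list 0.925 with a mean of 0.13 and the fibroblast list 0.711 with a mean of -0.13, and with the luminal markers as a covariate the fibroblast list had a mean of -0.05 (adjusted p = 0.862) and the macrophage list -0.12 (adjusted p = 0.213). The matrix protease and inhibitor list rose (25 members, mean 0.28, adjusted p = 0.0361, and adjusted p = 0.386 with an estimated correlation). Of these, the metalloprotease Adam9 rose 1.81-fold and 24 did not pass, and 2 rose adjusted over the list alone. Its adjusted p was 0.543 with the beta-actin covariate, 0.127 with no filter, 0.0821 with quantile normalization and 0.116 with the fibroblast covariate, and 0.0607, 0.213, 0.0744 and 0.0787 without knockout tumours 3 and 6 and wild-type tumours 1 and 3.

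The series title concerns metastasis, and the integrin and mesenchymal transition lists, which bear on adhesion and invasion, did not pass as a whole. The matrix protease and epithelial junction lists, described above with their limits, did pass by the same test. The integrin and focal adhesion list had a mean log2 change of -0.02 (23 members, adjusted p = 0.774), with the galectin Lgals3 2.27-fold higher. The mesenchymal transition list had a mean of -0.25 (17 members, adjusted p = 0.807), with the growth factor receptor Fgfr1 falling (log2 change -2.70) and Vim, also in the basal list, at a change of 0.03 (adjusted p = 0.944). Chemokine genes (mean 0.17, adjusted p = 0.453) included Ccl28, which passed adjusted over the list alone and was at background in all 6 wild-type and 2 of 6 knockout tumours. The Wnt target list (mean 0.09, median -0.01, test direction down, adjusted p = 0.829) held a rise of Sfrp2 and a fall of Sox4, and 1 rose and 3 fell adjusted over the list alone, Tnfrsf19 and Ccnd1 among them. Of 25 apoptosis and p53 target genes (mean -0.19, adjusted p = 0.519), the death-pathway gene Bid was 3.92-fold lower. The AMPK and Snf1-related kinase list had a mean of 0.05 (11 members, adjusted p = 0.644), with 0 members past the threshold.

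**Figure D3:**
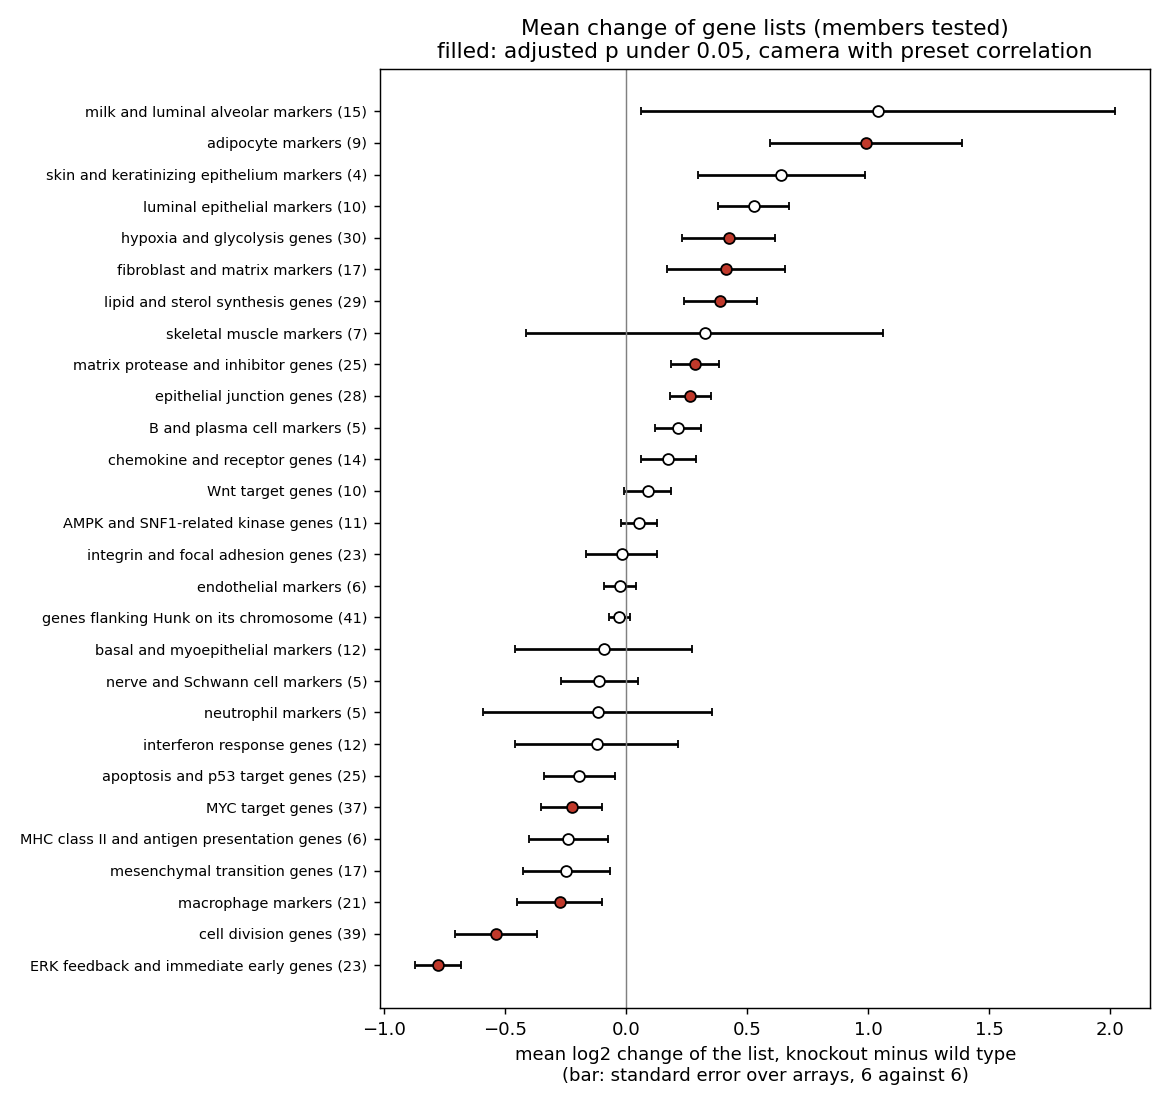
Mean log2 change, knockout minus wild type (horizontal axis), of the gene lists reported here with the number of members tested; bars are standard errors over 6 against 6 arrays, and filled points mark lists with an adjusted p under 0.05 by camera with the preset correlation. The ERK feedback list lies lowest at -0.78 and the milk list highest at 1.04, the latter with an open point and a wide error.

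Of 29 lists tested, 6 rose and 4 fell. With an estimated correlation between genes 0 of the 10 passed, and fry, which tests the members alone, passed 5 lists, 4 of these 10 (cell division, adipocyte, ERK feedback and epithelial junction) and the luminal markers. An exact permutation test of each list's mean over the arrays, added after seeing the data, gave its lowest p for the ERK feedback list (0.00216, the smallest possible), and 0 of 29 lists passed it after Benjamini-Hochberg adjustment, where 0.0628 is the lowest value that a single list can reach with 6 against 6 arrays, so that this says little against the ERK feedback list. The remaining lists did not pass camera, with mean log2 changes of 0.21 for B and plasma cell (adjusted p = 0.227), 0.64 for skin (adjusted p = 0.438), 0.32 for skeletal muscle (adjusted p = 0.453), -0.24 for antigen presentation (adjusted p = 0.644), -0.12 for interferon response (adjusted p = 0.774) and -0.03 for endothelial genes (adjusted p = 0.979). The neutrophil (-0.12), nerve (-0.11) and basal (-0.09) lists had adjusted p-values of 0.979, 0.988 and 0.989, and in these 3 and the Wnt list the mean, median and test differed in sign. The T and NK cell, mast cell and red blood cell lists had 3, 1 and 2 members above the expression filter and were not tested.

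The knockout allele was built from a genomic library of another mouse strain in embryonic stem cells, so neighbouring sequence that differs from FVB can travel with it. Of 46 tested genes within 10 Mb of Hunk on chromosome 16, 3 passed, namely Ttc3 (log2 change -1.38), the chromatin protein Hmgn1 (-0.42) and the serine protease Tmprss2 (1.93, named because the count is small). That is 6.52% against 3.32% of the other 6769 genes, an odds ratio of 2.03 with a 95% confidence interval of 0.40 to 6.41 (Fisher's exact test, two-sided, p = 0.199). The odds ratio was 3.22 without wild-type tumour 4, 3.16 without wild-type tumour 5 and 3.35 with no expression filter (Fisher's exact test, p = 0.137, 0.0788 and 0.0668), and over all alternatives it lay between 0 and 3.35. Within 2 Mb 0 of 19 genes passed (odds ratio interval 0 to 6.22, Fisher's exact test, p = 1). On the whole chromosome 8 of 217 did (odds ratio 1.11, Fisher's exact test, p = 0.701), among them Etv5, Pkp2 and Bdh1, farther than 10 Mb from Hunk. The list of genes flanking Hunk had a mean change of -0.03 (41 members, adjusted p = 0.829), with Ttc3 and Hmgn1 the 2 that passed.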

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

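The tests with the beta-actin covariate, with knockout tumours 4 and 5 averaged, of fibroblast minus macrophage means, along the beta-actin difference within groups and of the share of the change kept were chosen after the results were seen; the fibroblast and luminal covariate fits were planned, but their use as tests of these explanations was also chosen afterwards. In 240 tests of single arrays within groups of 6, 17 values, on 8 of the 12 arrays, lay far from the rest of their group, where chance alone gives about 1 in 20, or 12. Knockout tumour 3 had a skeletal muscle marker mean of 8.39 against 4.25 to 4.65 in the other knockout tumours, and wild-type tumour 1 had 6.19 against 4.13 to 4.85. Knockout tumour 3 also had the highest background (4.00) and stood apart for Myoz1 (5.57) and Bsg (10.13). Knockout tumour 1 stood apart in 5 values, namely Col9a1 (3.65 against 8.43 to 9.09), Chpt1 (11.26, high), Cd24a (11.61, low), C1qa (8.61, high) and the basal marker mean (5.13, low). Knockout tumour 4 was lowest for Hunk (2.60). In the wild type, tumour 3 was high for Sfrp2 (7.06 against 2.75 to 3.45), tumour 2 low for Chdh (2.91) and Rhou (6.81), tumour 5 low for C1qb (8.06) and Fabp4 (5.17), and tumour 6 high for the skin marker mean (5.73). Of 64 control probe sets outside the comparisons, some of them for mouse transcripts, 4 had an unadjusted exact permutation p under 0.05. Among these were pyruvate carboxylase probe sets, the 3' one 0.86 higher in the knockout on the log2 scale, so they are not purely a technical check. After adjustment 0 passed, which says little, since a single probe set could not pass with so few arrays.

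Other splits of the arrays bear on the counts. Of the 462 possible splits of the 12 arrays into 6 and 6, 100 were drawn, the real one included. Of these, 1 gave as many genes as the real 228, and the highest of the others gave 27. That split differed from the real one by 1 array exchanged each way, and others at that distance gave 0 or 1. The next highest count was 2, and 95 of the other splits gave 0 genes. The real count thus lay far above the others drawn. Since 1 of 100 is the smallest share this test can give, chance is not fully excluded for the gene count. The splits also treat all 12 arrays as separate samples, which the closest pair of knockout arrays may not be. For probe sets 1 of 100 reached the real 278, with the highest other at 32. For gene lists 7 of 100 reached the real 10 and the highest other gave 12, so chance cannot be excluded for the number of lists.

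The list of ERK feedback and immediate early genes was lower in the knockout, through 5 of its 23 members, while 18 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.0936); the fits that follow used the preset correlation. A difference in RNA quality is argued against, since with the beta-actin difference as a covariate the list kept its change (-0.79, SE 0.15, adjusted p = 0.00589). A shift in fibroblast content is argued against, since with the fibroblast covariate the list kept its change (-0.82, SE 0.11, adjusted p = 0.0011). The fibroblast mean itself did not clearly differ between groups (exact permutation p = 0.119). Other stromal cells are not covered by that fit. With knockout tumours 4 and 5 averaged the adjusted p was 0.000894. Camera sets the list against the other genes, so that fit could hardly show the effect of 1 tumour counted as 2. The list mean was 6.27 to 6.36 in the other knockout tumours and 6.86 to 7.43 in the wild type. The fall therefore did not rest on this pair, while other shared origins of arrays could not be checked. It may be that tumours without Hunk carry lower ERK output, or that wild-type tumours more often gained another change in the Ras pathway during growth. The arrays hold no measure of mutation or of ERK itself, so these stay open.

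The cell division list fell and the fibroblast list rose by camera with the preset correlation, although 0 of 17 fibroblast markers passed and neither list passed with an estimated correlation. A lower share of tumour cells is not settled, since the macrophage list fell but the change in fibroblast minus macrophage means had an exact permutation p of 0.0952. A difference in RNA quality could account for part of it, since with the beta-actin covariate the change went from -0.54 (SE 0.17) to -0.17 (SE 0.21, adjusted p = 0.156), so the call ended because the change shrank. Whether the list follows the beta-actin difference within groups was tested in 2 ways that differ: camera with the preset correlation, run first, gave p = 2.08e-07 for a fall, and a permutation over arrays, chosen after that value was seen because camera passed a median of 5 lists in other splits, gave a Pearson r of -0.63 (n = 12, permutation p = 0.0799) and a Spearman rho of -0.22 (permutation p = 0.518), with r -0.54 without the 2 farthest arrays. The first would count RNA quality as a cause that the data bear out and the second leaves it undecided, so RNA quality and genotype cannot be told apart here.

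The gene count fell to 4 with the luminal marker mean as a covariate, where Cbr2, Hp, Spry2 and Lpcat1 (named because the count is small) passed. Over the 228 genes the median share of the log2 change kept was 87.3%, all 228 kept their sign, and the standard errors grew by a median of 1.51 times. A loss of precision, from a covariate that itself differed between groups (exact permutation p = 0.00866), may be part of the cause. It may not be all of it, since the beta-actin covariate raised the standard errors as much. With that covariate 72 genes passed and a median of 104% of the change was kept. Whether luminal identity and genotype act separately was not tested.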

How the results depend on the processing

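Choices marked as added were made after seeing the data. Of 228 genes and 278 probe sets, 112 and 152 passed with no filter, 402 and 602 with array weights, 113 and 150 with the fibroblast covariate, 4 and 4 with the luminal covariate, 354 and 504 with the residual component, 463 and 666 at adjusted p under 0.10, 143 and 176 at 2-fold or more, and 36 and 60 with each probe set tested on its own variance. Added choices gave 124 and 172 with knockout tumours 4 and 5 averaged and 72 and 104 with the beta-actin covariate. The luminal and beta-actin covariates lower precision (standard errors of the 228 genes a median of 1.51 times larger with each). That alone may not account for counts as unlike as 4 and 72 genes. The averaged fit has fewer samples, and for the other settings the cause was not tested. Of the 228 genes, 109 also passed with no filter, 91 with the fibroblast covariate and 63 with the replicate block. With the added covariates 104 also passed for adipocyte markers, out of 189, and 46 for beta-actin. Leaving out 1 array gave 94 to 210 genes and 132 to 318 probe sets, with 94 and 132 without wild-type tumour 4, 131 and 171 without knockout tumour 6, 134 and 162 without knockout tumour 5, 137 and 170 without knockout tumour 4, 149 genes without wild-type tumour 5 and 184 probe sets without wild-type tumour 6.

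The list count went from 10 to 5 with the beta-actin covariate, 5 with fry and 0 with an estimated correlation, and lay between 9 and 11 without 1 array. Over all alternatives the adjusted p ranged from 2.77e-18 to 0.386 for cell division, 0.000102 to 0.678 for ERK feedback, 0.000469 to 0.386 for epithelial junction, 0.000109 to 0.862 for fibroblast, 0.000732 to 0.925 for macrophage, 5.79e-05 to 0.451 for adipocyte and 0.0122 to 0.543 for matrix protease genes. The fibroblast list reversed with the beta-actin covariate (mean -0.13, adjusted p = 0.711). Means of lists past the threshold also changed sign for macrophage genes with that covariate (0.13) and for fibroblast genes with the luminal covariate (-0.05). Of 566 comparisons of lists with an alternative, 525 kept direction and side of the threshold or were not past it in either, 34 lost and 6 gained the threshold; of 1499 for named genes 226 lost it, 24 gained it and 0 reversed. Hunk stayed lower and not past the threshold in every fit (change -0.62 to -1.71), and genes near Hunk stayed not past the threshold.

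Whether the replicate numbers pair the arrays was not tested, and the values below show no clear pairing but do not exclude it. Correlations of deviations were -0.02 to 0.14, over 0.1 in 2 of 6 pairs. Of the knockout arrays, 3 of 6 correlated best with their own number, more than unrelated numbers would give on average. With the replicate block 69 genes and 112 probe sets passed and 11 lists, the milk list among them (adjusted p = 0.0325), and the odds ratio near Hunk was 0.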

Other observations

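The test of Hunk against ERK feedback genes was chosen after the results were seen. Some milk and luminal markers differed widely between knockout tumours, although the luminal list mean lay between 8.46 and 9.15. The milk list mean was 9.41, 9.80 and 10.02 in knockout tumours 2, 3 and 6 and 5.88, 5.98 and 5.85 in knockout tumours 1, 4 and 5. Csn3 was above 13 in the former 3 and between 5.48 and 7.37 in the latter, and Kit, a receptor of luminal progenitors, was 4.05 to 4.60 in the former and 7.75 to 8.81 in the latter. The milk list mean differed between wild-type tumours too, at 8.46 and 7.94 in tumours 2 and 3 and 5.81 to 6.55 in the others. Wild-type tumours had a Csn3 level of 11.15 to 13.88 and a Kit level of 8.56 to 10.05. Their Krt19 (3.30 to 9.13) and Ltf (2.55 to 11.39) levels spread more widely than those of the knockout tumours. The luminal marker Krt19 was 11.22 to 12.51 in knockout tumours 2, 3 and 6 and 8.22 to 10.54 in knockout tumours 1, 4 and 5, unlike Kit. The milk marker Ltf was highest in knockout tumour 1 (12.77) among the knockout tumours. No label separates these knockout tumours, and no test was made between them. Knockout tumours 4 and 5 were the closest pair of arrays and may not be separate samples.

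A hypothesis was that ERK feedback genes follow the Hunk level among wild-type tumours. Over the 6 wild-type arrays the list mean had a Pearson r of 0.53 with Hunk (n = 6, exact permutation p = 0.289) and a Spearman rho of 0.37 (exact permutation p = 0.497), the only such relation computed. Without the 2 arrays farthest from the median Hunk level r was -0.68, so the relation rests on those arrays and these data do not decide it.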
